A study of Mus musculus with 2 samples.

How the data were processed

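Lineage-negative Kit-positive fetal liver cells of E14.5 embryos were measured in 2 libraries, 1 from Brd9 knockout and 1 from control embryos. Libraries used the 10x Genomics 3' chemistry, per the labels' protocols. The authors used Cell Ranger 7.2.0 and the mm10 build, per the submitters' processing notes, and deposited a matrix of UMI counts per gene and barcode. The deposited counts were whole numbers with no normalization. Whether intronic reads were counted is not given in the sources used here. Features and barcodes were named in separate deposited lists, and both libraries listed the same 32285 genes. Of their identifiers, 32235 were in the GENCODE M21 annotation of the same build, which supplied coordinates.

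Cells were kept with at least 1000 genes, at least 2000 UMIs and at most 10% mitochondrial UMIs. This kept 7001 knockout and 7100 control barcodes and left out 288 and 299. Scrublet in scanpy 1.11.5, run per library with an expected rate of 6%, marked 247 (3.53%) and 218 (3.07%) cells as doublets, which were removed. Its automatic thresholds were 0.25 and 0.265. Cells with at least 3 Xist and 3 Y-linked UMIs, 226 in the knockout and 164 in the control, had a median of 71951 and 75837 UMIs, against 36118 and 38796 in female cells, and a median of 17.5 and 18.5 Xist UMIs, against 18 and 20. This comparison was added after seeing the data. They were taken as doublets of embryos of different sex, and Scrublet had marked 37.6% and 42.1% of them. If all the others were such doublets, 4.38% of kept knockout and 3.86% of kept control cells would be doublets.

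Both libraries were clustered together without integration, on 3000 highly variable genes chosen within each library, 30 principal components and 15 neighbours, with Leiden resolution 1. S-phase, G2/M, sex-linked, mitochondrial and ribosomal protein genes and Brd9 were left out. The 24 clusters were named from 18 marker lists, by the list with most members among the top 30 genes by fold, or by the highest relative marker level where no list had 2 of them, and early and late erythroid clusters were merged. No cluster of a compared class had more markers of another class than of its own among its top 10 genes. Erythroid clusters 1, 2, 4, 6, 8 and 23 had 0 of either there. Cluster 11, named megakaryocyte-erythroid progenitor, and cluster 14, named monocyte, had 1 of each. Classes with at least 150 cells in each library, 6 in all, were compared. Names rest on these rebuilt clusters and stand for cells like the named type.

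UMIs were summed per library, or per class and library, and given as CPM, the count scaled to a library total of 1e6. The log2 ratio is knockout over control, with the conditional exact interval. Summed counts have exact Poisson intervals and shares exact Clopper-Pearson intervals, at 95%, while ratios of shares have log-normal intervals. For a count of 0 the planned floor was 3 counts, below the upper limit of its exact interval. For the share of cells with a UMI, each cell was thinned to 18501 UMIs, percentile 5 of kept cells. Cell sex was taken from Xist, as female with at least 3 UMIs and at most 1 Y-linked UMI over 4 genes, and male with at most 1 Xist UMI. This rule was set after seeing the data. A first rule that also required Y-linked UMIs for male cells left out 52 of 251 control and 13 of 92 knockout cells of the S100a8-led cluster and was replaced.

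Before the data were examined, 34 gene lists, the markers, the alternatives and the rule for named genes were fixed. The rule named the 12 highest and 12 lowest log2 ratios among genes with at least 20 CPM in either library. It named the 12 highest and 12 lowest by weakest ratio among genes with the same direction in all compared classes. It named 4 in each direction per class with at least 50 CPM, and up to 4 members per list. Brd9, other BAF subunits, Kit and globins were always named. Some genes that the rule names are not reported. Xist, Tsix, Y-linked, mitochondrial, ribosomal protein and predicted genes were left out of these parts except that on lists, while other X-linked genes were kept. A list median was set against 10000 random lists matched in 20 expression bins.

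The ratio step was tested on simulated data of 6120 genes, with 50 genes changed at each of 4 folds. The interval held the true value for 96% of genes changed 0.25-fold, and for 98% at each of 0.5-fold, 2-fold and 4-fold. Among 200 random lists in data with no shift, 5.5% fell outside the central 95%. The simulated counts were Poisson draws and the lists were drawn at random. The test therefore checks the calculation only, not UMIs that gather in few cells or list members that vary together. Alternatives covered resolution, doublets, stricter filters, cell-cycle genes, projection on control clusters, scaling, minimum level and class reweighting. Added after seeing the data were clustering without 343 marker and differing genes, female or male cells alone, cells with transcripts of both sexes left out, and each named gene without the cell with most of its UMIs in each library. The 100 CPM minimum was not applied to single genes, whose value it cannot change. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.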

Results

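Single cells from mouse fetal liver at E14.5 were profiled by droplet RNA sequencing after enrichment for lineage-negative cells that carry the Kit receptor, a gate that holds blood stem and progenitor cells. One library came from embryos in which Vav1-iCre, a recombinase active in blood cells, was combined with floxed Brd9. The control library carried floxed Brd9 without the recombinase. The comparison asks what loss of Brd9 changes in these cells, but no library carried the recombinase without floxed Brd9. Effects of the recombinase or its transgene therefore cannot be told apart from loss of Brd9. Brd9 encodes a bromodomain subunit of the non-canonical BAF chromatin remodelling complex. The knockout library held 7289 barcodes with 271350214 UMIs and the control library 7399 barcodes with 292972312 UMIs. After filtering, 6754 knockout and 6882 control cells remained, with a median of 36001.5 and 38508 UMIs and of 5952.5 and 6037 genes per cell. There was 1 library per genotype, so no difference below has a replicate check and no p-value is given. All intervals are 95% intervals that cover counting error only. The number of embryos behind each library is not given in the sources used here. Xist marked 58.9% of knockout cells (57.7 to 60.1) and 22.9% of control cells (21.9 to 23.9) as female, so each library held embryos of both sexes in a different mix.

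Brd9 was lower in the knockout library in each of the 6 cell classes compared. It stood at 7.07 CPM (6.74 to 7.40, 1796 UMIs) in the knockout and at 27.2 CPM (26.6 to 27.8, 7510 UMIs) in the control, a 3.85-fold lower level (3.66 to 4.06) and a log2 ratio of -1.95 (-2.02 to -1.87). The log2 ratio of Brd9 was -2.06 in erythroid cells, -2.04 in megakaryocyte-erythroid progenitors (MEP), -1.46 in mast and basophil cells, -1.43 in granulocyte-monocyte progenitors (GMP), -1.27 in stem and multipotent progenitors (HSC/MPP) and -1.08 in the monocyte class. Brd9 (ENSMUSG00000057649) lies on chromosome 13 from 73937811 to 73960895 in mm10 coordinates. After thinning to 18501 UMIs per cell, 11.9% of knockout and 38.8% of control cells had a Brd9 UMI, with 365 and 316 shallower cells left out. Without thinning the shares were 21.5% and 62.2%. Alb, a hepatocyte gene that blood cells should lack, had a UMI in 1.88% and 2.51% of all cells. Tags at the 3' end may lie outside the floxed exons, so the remaining Brd9 UMIs do not measure intact transcript.

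**Figure D1:**
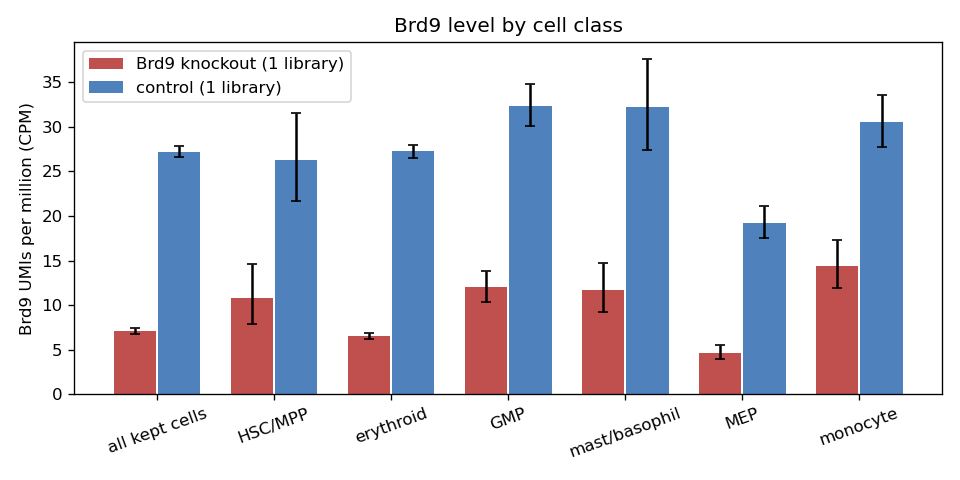
Bars give Brd9 CPM in all kept cells and in 6 cell classes, for 1 knockout and 1 control library, with exact Poisson 95% intervals of the summed counts. The knockout bar is at 7.07 CPM and the control bar at 27.2 CPM in all kept cells, and the knockout bar is the lower in each class.

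Bicral and Bicra, the measured subunits besides Brd9 that are specific to the non-canonical complex, were higher in the knockout library. Bicral was at 43.4 against 27.6 CPM (log2 ratio 0.65, 0.61 to 0.69) and Bicra at 30.7 against 24.0 CPM (0.36, 0.31 to 0.40). Bicral and Bicra were higher in each class compared, and Bicral gave 0.64 within female and 0.67 within male cells. Of the 19 measured subunits of the other BAF and PBAF complexes, 16 were above and 3 below 0, and 0 were beyond 0.5 on the log2 scale. Bcl7b gave 0.16, Bcl7a 0.11, Smarcd1 0.10 and Bcl7c 0.09, whereas Smarca4, the ATPase, gave 0.04. The 3 subunits below 0 were Smarcc1 at -0.08, Phf10 at -0.06 and Brd7 at -0.04. Their median of 0.04 lay at percentile 84.0 of 10000 random lists matched on expression.

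The share of the granulocyte-monocyte-lymphoid lineage was lower in the knockout library, and the shares of megakaryocyte and MEP cells and of mast and basophil cells were higher. In the main clustering this lineage held only GMP and monocyte clusters, and no cluster was named lymphoid-primed. The granulocyte-monocyte-lymphoid lineage made up 11.96% of knockout cells (11.2 to 12.8) and 16.8% of control cells (15.9 to 17.7), a ratio of 0.714 (0.657 to 0.776). The megakaryocyte and MEP lineage made up 14.2% (13.4 to 15.1) and 10.2% (9.50 to 10.9), a ratio of 1.39 (1.27 to 1.53). Mast and basophil cells made up 3.67% (3.24 to 4.15) and 2.46% (2.10 to 2.85), a ratio of 1.50 (1.23 to 1.81). Erythroid cells made up 67.3% (66.1 to 68.4) and 67.6% (66.4 to 68.7), and HSC/MPP 2.86% (2.47 to 3.28) and 2.98% (2.59 to 3.41), differences that were not detectable at this depth. That call depends on the settings, since the erythroid ratio was 0.952 (0.916 to 0.988) among female cells and 0.946 (0.922 to 0.970) with cell-cycle genes kept in the clustering, where the HSC/MPP ratio was 0.840 (0.746 to 0.946). The sort on Kit and against lineage antigens sets which cells could be counted.

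Genes that define some of these classes differed between the libraries, so the cells were also clustered without class markers and without genes that differed, a choice made after seeing the data. The granulocyte-monocyte-lymphoid lineage then made up 10.2% of knockout (9.48 to 10.9) and 14.9% of control cells (14.1 to 15.8), a ratio of 0.682 (0.623 to 0.747). Megakaryocyte and MEP cells made up 14.1% and 9.42%, a ratio of 1.49 (1.36 to 1.64), and mast and basophil cells 4.49% and 2.92%, a ratio of 1.54 (1.29 to 1.83). HSC/MPP made up 4.29% and 4.52%, and erythroid cells 66.98% and 68.2%. In this clustering a GMP cluster led by S100a8, Stfa1 and S100a9 held 84 knockout and 229 control cells, a larger one led by Mpo and Prtn3 held 412 and 564, and a lymphoid-primed cluster held 192 and 235. In the main clustering the larger GMP cluster held 441 and 483, a ratio of 0.930 (0.821 to 1.05), so its lower share depends on the clustering. The S100a8-led cluster of the main clustering held 92 and 251 cells. The monocyte class of the main clustering was a single cluster that also expressed Ighm, at 74.9 and 79.5 CPM, and Flt3, at 85.7 and 72.2 CPM, where Ighm is a B-lymphoid gene and Flt3 a receptor of multipotent, lymphoid-primed and some myeloid progenitors. At resolution 0.6 and without markers no cluster was named monocyte. A cluster led by Lsp1 and Hdac9, also among the top genes of the monocyte class, was named lymphoid-primed there, so the name monocyte depends on the clustering. In the main clustering, erythroid clusters 0 and 6 held 575 and 430 knockout cells against 20 and 18 control cells, and clusters 3 and 23 held 51 and 60 knockout cells against 573 and 624 control cells, so these clusters may follow the library rather than a cell type. Other erythroid clusters differed in share too. Clusters 4 and 1 had ratios of 2.06 (1.80 to 2.36) and 1.91 (1.64 to 2.24). Clusters 5, 18, 7 and 17 had 0.400, 0.543, 0.667 and 0.851, each with an interval below 1. The like erythroid shares thus do not show that shares inside the lineage were alike. Among female cells of the main clustering the granulocyte-monocyte-lymphoid ratio was 0.895 (0.766 to 1.04) and among male cells 0.723 (0.644 to 0.812). Control female and control male cells, which come from different embryos, differed in this share by a ratio of 0.713 (0.619 to 0.821), as far from 1 as the ratio between the genotypes, and knockout female and male cells by 0.882 (0.773 to 1.01).

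**Figure D2:**
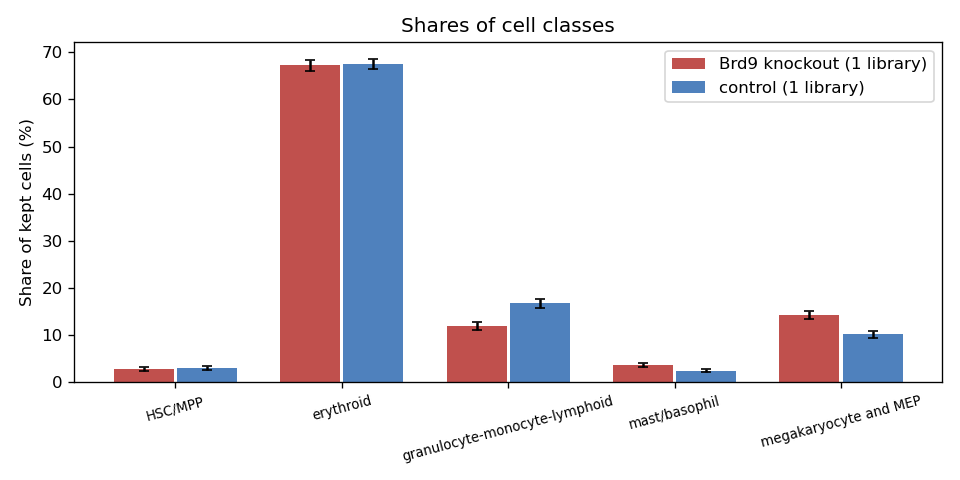
Bars give the percent of kept cells in each of 5 lineages for 1 knockout and 1 control library, with exact Clopper-Pearson 95% intervals. The granulocyte-monocyte-lymphoid share is 11.96% in the knockout and 16.8% in the control, and the megakaryocyte and MEP share is 14.2% and 10.2%.

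Over the whole library, Camp, F13a1, Hp and Elane had the lowest log2 ratios, and Meis1, Gcat and Prkca were among the highest. Camp, an antimicrobial peptide of neutrophil granules, was at 3.81 against 46.3 CPM (log2 ratio -3.60, -3.70 to -3.51), and 1 cell held 29.8% of its knockout UMIs. F13a1, a coagulation factor subunit made by monocytes, gave -2.66, Hp, haptoglobin, -2.13, and Elane, neutrophil elastase, -2.08. Ms4a3 gave -1.15, Ctsg, cathepsin G, -1.09 and Cstdc4 -1.32. Also among the lowest, Hbb-bt, an adult beta globin, gave -1.94, Ifitm1 -1.76, Smim5 -1.37 and Sphk1, sphingosine kinase, -1.21. Among the highest, Meis1, a transcription factor of stem and progenitor cells, was at 59.5 against 32.3 CPM (0.88, 0.84 to 0.92), and Gata2, a progenitor transcription factor, gave 0.68. Gcat gave 0.85, Prkca 0.78, Commd10 0.78, Slc22a3 0.71, Pfkp 0.71, Spns2 0.68 and Pf4, platelet factor, 0.66.

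Whole-library ratios mix class shares with levels inside cells, and they also carry the sex mix. Within female and within male cells, Elane gave -1.24 and -2.01, Ms4a3 -0.67 and -0.94, and Pf4 1.41 and 0.27. Mid1, an X-linked gene with the highest ratio of 2.49, was at 18.0 CPM in control female and 0.22 CPM in control male cells, against 26.9 and 22.1 CPM in the knockout. Pold2, a DNA polymerase subunit with a ratio of 0.82, was at 68.5 and 38.8 CPM in control female and male cells, against 80.9 and 80.5 CPM. Mid1 and Pold2 thus differed between the libraries within male cells, which argues against the sex mix as their whole cause. Over 6223 genes with at least 20 CPM, the 5th and 95th percentiles of the log2 ratio were -0.15 and 0.18, and the median was 0.03.

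Apoe, the apolipoprotein of cholesterol transport, and Hbb-bt were the lowest in rank among genes with the same direction in each class. Outside erythroid cells Hbb-bt UMIs may be free erythroid RNA, so its rank does not show a change inside each class. Apoe gave -1.04 over the library, from -1.06 in HSC/MPP to -1.55 in mast and basophil cells. Kcnn4, a calcium-activated potassium channel, gave -0.51 over the library and Cox6b2 -0.52, with Hmgn2, a nucleosome-binding protein, at -0.45. The other 7 of this group, Cenpv, Dhps, Frat2, Bst2, Plscr3, Golim4 and Prdx6, lay between -0.26 and -0.16 over the library. Bicral and Commd10 ranked highest, and Commd10 ranged from 0.49 in erythroid cells to 1.96 in mast and basophil cells. Xrcc4, a DNA end-joining factor, gave 0.55, Cbfa2t3, a transcriptional corepressor, 0.40, Rinl 0.33, Mnd1 0.35, Tbc1d1 0.31, Abcc1 0.31 and Sipa1 0.25. Kdm6a, which escapes X inactivation, gave 0.40 over the library but 0.07 within female and 0.09 within male cells.

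**Figure D3:**
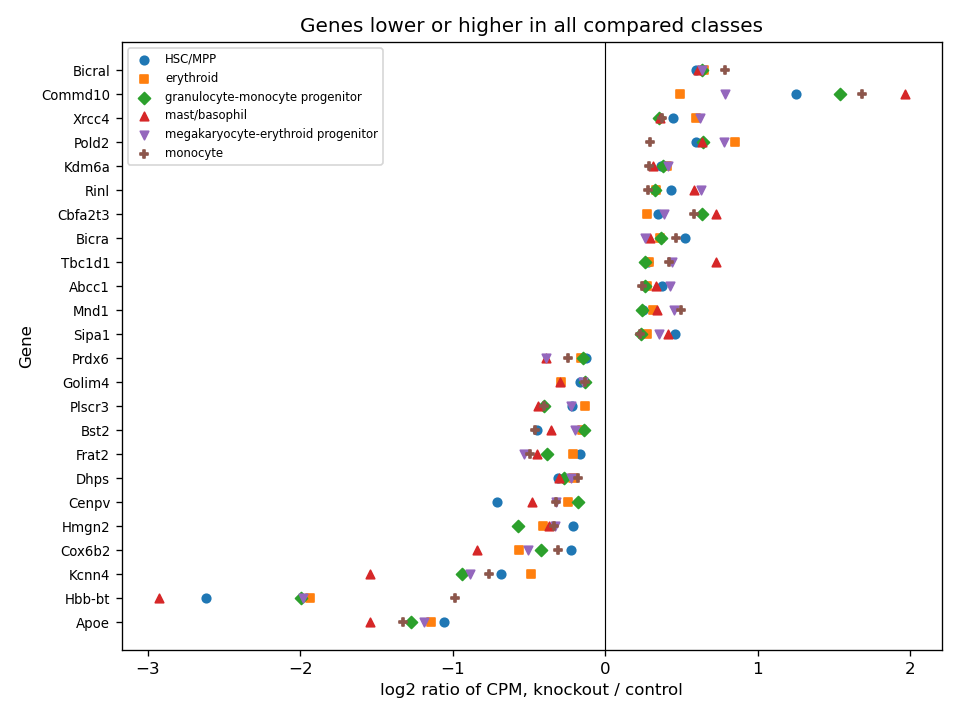
Points give the log2 ratio of CPM, knockout over control, of 24 genes in each of 6 cell classes, each class with its own marker shape and 1 library per genotype. Apoe, Hbb-bt and Kcnn4 lie left of 0 and Bicral, Commd10 and Xrcc4 right of 0 in each class.

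Within the classes, Hbb-bt was among the 4 lowest in erythroid, MEP, HSC/MPP and mast and basophil cells, and Commd10 among the 4 highest in GMP, HSC/MPP and mast and basophil cells. Outside erythroid cells Hbb-bt had a UMI in 18.1% to 34.0% of thinned knockout and 53.8% to 75.7% of thinned control cells. Part of these UMIs may be free erythroid RNA, so the Hbb-bt values there are not read as levels of those classes. In HSC/MPP Hbb-bt stood at 68.1 CPM in the knockout and 418 CPM in the control. The other non-erythroid classes had at most 29.5 and 102 CPM, which argues against free RNA as the whole source in HSC/MPP. In erythroid cells the lowest were Hbb-bt at -1.94, Ifngr1, an interferon receptor chain, at -1.10, C1qtnf12 at -0.94 and Sh2d4a at -0.94, and the highest Tmsb4x, an X-linked actin-binding peptide, at 1.05, Pkm, pyruvate kinase, at 0.88, Pold2 at 0.85 and Kcnq5 at 0.84. In MEP the lowest were Hbb-bt at -1.98, Muc13 at -1.85, Apoe at -1.19 and Dach1 at -1.16, and among the highest were Plek at 0.93, Cacnb2 at 0.89 and Meis1 at 0.84. Apoe is among the markers that named the MEP class. In GMP the lowest were Camp at -3.51, Stfa3 at -2.79, F13a1 at -2.31 and Fcnb at -2.21, and the highest Commd10 at 1.54, Gata2 at 0.96, Auts2 at 0.95 and Hba-a1 at 0.91. Hba-a1 had a UMI in 44.3% and 35.7% of thinned GMP and in 44.0% and 35.2% of thinned cells of the monocyte class, which should lack it, at median depths of 28274 and 29452 UMIs in GMP and 27844 and 33620 in monocytes. Hba-a1 is therefore not read as expression in GMP. The GMP values hold the smaller S100a8-led cluster at its different share in each library, and the erythroid values hold the library-specific clusters 0, 3, 6 and 23.

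In HSC/MPP, with 193 knockout and 205 control cells, the lowest were Chgb at -7.71, Hbb-bt at -2.62, Cd27 at -1.65 and Il12a at -1.27, and the highest Npas3 at 2.97, Fam155a at 2.72, Bank1 at 1.43 and Commd10 at 1.25. Of these, Chgb rested on 1 knockout UMI in 1 cell and 227 control UMIs in 1 male cell, so it is not read as a level of the class. Npas3 had 79.0% of its knockout UMIs in 1 cell and gave 1.09 without the top cell of each library, a check added after seeing the data. Chgb, Il12a, Npas3, Fam155a and Bank1 were under 4 CPM over either whole library. In mast and basophil cells the lowest were Dach1 at -3.56, Muc13 at -2.99, Hbb-bt at -2.93 and Apoc1 at -2.37, and the highest Commd10 at 1.96, Mirt1 at 1.42, Tgfbr1, a transforming growth factor receptor, at 1.17 and Alox5, a lipoxygenase, at 209 against 104 CPM. Erythroid genes and the class's own genes were lower there too. Lower were 5 of 6 erythroid membrane genes (median -1.93), 9 of 10 heme and iron genes (-0.31), 9 of 11 erythroid transcription factors (-0.35) and 5 of 6 mast cell and basophil genes (-0.65), each list at percentile 0. The class was a single cluster with 2 of its own and 2 of another class's markers among its top 10 genes. A different mix of cells in each library cannot be told apart from levels inside these cells. In the monocyte class the lowest were F13a1 at -2.09, Ccr2, a chemokine receptor, at -1.60, Hp at -1.53 and Ifitm1 at -1.47, of which F13a1 and Ccr2 are among the markers that named the class. The highest there were S100a9 at 3.93, Cstdc5 at 2.46, S100a8 at 2.40 and Fam155a at 2.05, but 1 cell held 47.0% of the knockout UMIs of S100a9, 29.0% of those of S100a8, 24.7% of those of Cstdc5 and 23.9% of those of Fam155a, which had UMIs in 13 knockout and 17 control cells. S100a9 turned to -0.45 when classes were taken from control clusters, and S100a8 turned to -0.10 in female cells.

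Neutrophil granule genes were lower and glycolysis genes higher as groups, and stem cell genes went both ways. All 9 measured primary granule genes were lower, 6 of them beyond 0.5, with a median of -0.89 at percentile 0 of the random lists. With knockout classes reweighted to the control shares this median was -0.48. All 3 measured secondary granule genes were lower, with a median of -0.94, S100a9 at -0.94 and S100a8 at -0.83, but the median was -0.22 within female and -0.53 within male cells, where S100a8 gave -0.20 and -0.36. Of 11 measured stem cell genes 7 were higher and 4 lower, 3 of them higher beyond 0.5, with a median of 0.19 at percentile 100, but the median was 0.01 among members with at least 100 CPM, and 3 of 5 members were lower in erythroid cells (-0.07, percentile 2.60). In the other classes the median was above 0, from 0.08 in HSC/MPP (14 of 20 higher, percentile 97.8) to 0.28 in MEP (8 of 11 higher, percentile 100). All 15 glycolysis genes were higher over the whole library, with a median of 0.13 at percentile 100. Pfkp gave 0.71, Pkm 0.52, Aldoa 0.35 and Eno1 0.32. By class the median lay above the random range in erythroid cells (0.13), GMP (0.14) and MEP (0.08, 10 of 15 higher). It lay within that range in HSC/MPP (0.06, percentile 95.4), mast and basophil cells (0.09, percentile 97.0) and monocytes (0.04, percentile 93.6).

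Red cell genes were mixed. Of 13 membrane and cytoskeleton genes 8 were lower and 5 higher, with a median of -0.12 at percentile 0, and -0.03 among members with at least 100 CPM. Slc4a1, the band 3 anion exchanger, gave -0.45, Add2 -0.43 and Tmod1 0.36. Of 13 heme and iron genes 10 were lower, with a median of -0.04 at percentile 0.45 and Urod at -0.25. Of 12 erythroid transcription factors 8 were lower, with a median of -0.03 at percentile 1.41, Sox6 at -0.44 and Zfpm1 at 0.20. Adult globins other than Hbb-bt were higher, Hba-a1 at 0.25, Hba-a2 at 0.33 and Hbb-bs at 0.24, although within female cells Hba-a1 gave 0.05 and Hbb-bs -0.11. In the classes other than erythroid, Hba-a1 had a UMI in 43.4% to 49.2% of thinned knockout and 35.2% to 41.1% of thinned control cells, like shares that are read as background, so the list is not compared there. Hbb-y, Hbb-bh1 and Hba-x, the embryonic globins, were under 3 CPM in both libraries. Kit, the sorting antigen, gave -0.07, with 63.7 and 66.9 CPM, Ptprc, the CD45 antigen, -0.17 and Vav1 0.09. By class Kit went both ways, at 0.44 in HSC/MPP, 0.002 in GMP, -0.07 in erythroid cells, -0.16 in monocytes, -0.32 in MEP and -0.41 in mast and basophil cells.

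Cell-cycle lists had medians near 0 over the whole library, and in the classes they were set against random lists but not against each other. The S-phase list had a median of 0.01 at percentile 23.0, with 18 members higher and 14 lower, and the G2/M list a median within 0.01 of 0, at percentile 8.54, with 16 higher and 19 lower. Over the whole library 0 members of either list were beyond 0.5. S-phase genes were higher for 30 of 32 members in GMP (median 0.12, percentile 100), 29 of 32 in mast and basophil cells (0.18, percentile 100), 26 of 32 in HSC/MPP (0.12, percentile 99.9) and 23 of 32 in MEP (0.04, percentile 99.1), and lower for 20 of 32 in erythroid cells (-0.01, percentile 2.40). In monocytes their median lay within the range of the random lists (-0.05, percentile 13.7). G2/M genes were higher for 33 of 35 members in GMP (0.10, percentile 99.7) and 32 of 35 in monocytes (0.15, percentile 100), and lower for 21 of 35 in erythroid cells (-0.02, percentile 0.365) and 22 of 35 in mast and basophil cells (-0.04, percentile 1.47), and lay within the random range in HSC/MPP and MEP. The p53 list had a median of 0.01 at percentile 27.0, and the apoptosis list 0.04 at percentile 61.4, with 5 of 7 members higher. All 6 measured cholesterol synthesis genes were higher, with a median of 0.14 at percentile 99.2, led by Cyp51 at 0.27. Of 7 immediate early and dissociation stress genes 4 were higher, with a median of 0.11 at percentile 99.3, Hsph1 at 0.15 and Jun at -0.12, while 6 of 7 were higher in GMP (0.14), 10 of 13 lower in mast and basophil cells (-0.18, percentile 0.10) and 7 of 9 in monocytes (-0.14, percentile 1.11). Of 5 unfolded protein response genes 4 were lower, with a median of -0.08 at percentile 1.26 and Xbp1 at -0.15. Ifitm3 gave -0.82 and Bst2 -0.26, the only 2 members of the fixed interferon response list with at least 20 CPM.

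**Figure D4:**
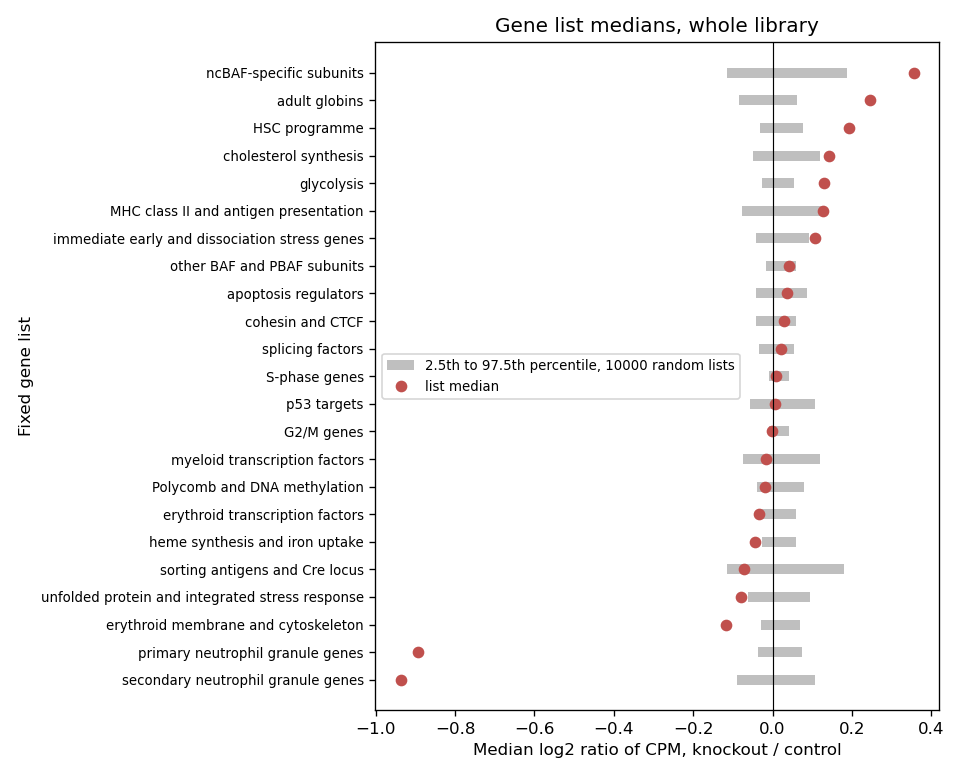
Points give the median log2 ratio of CPM, knockout over control, of each fixed gene list with at least 3 measured members, and grey bars the central 95% of 10000 random lists matched on expression. Primary granule genes lie at -0.89, left of their bar, and the stem cell programme at 0.19 and glycolysis at 0.13, right of theirs.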

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

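The tests of this part were chosen after the result was seen, except that of the genes around Commd10. Xist and Gm47283, which the whole-library and class comparisons leave out, were above the control level, while Eif2s3y, Ddx3y and Uty, Y-linked genes, were below it, at -0.98, -0.98 and -0.93. Xist was at 316 CPM in the knockout and 135 CPM in the control library, and Gm47283, a predicted gene that the annotation places on chromosome Y, at 140 and 34.0 CPM. Gm47283 was at 133 CPM in control female and 2.58 CPM in control male cells, against 154 and 118 CPM in the knockout. The HSC/MPP share ratio was 0.770 (0.556 to 1.07) in female and 1.17 (0.902 to 1.51) in male cells, on opposite sides of 1 with intervals that both include 1, and the difference was not tested.

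The granulocyte-monocyte-lymphoid share was lower in the knockout library. The different sex mix is argued against as the whole cause, since the ratio standardised to the control sex mix was 0.754 (0.684 to 0.830). Clustering on genes that differ between the libraries is argued against too, with a ratio of 0.682 (0.623 to 0.747) when they were left out. Variation between embryos cannot be told apart from the genotype: control female and male cells differed by a ratio of 0.713, against 0.714 between genotypes, knockout female and male cells by 0.882, and the number of embryos is not known. The loss of Brd9 stays open as well, and the recombinase, present only in the knockout, cannot be told apart from it.

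Commd10 was higher in the knockout library in each class compared. A widely used Vav1-iCre line carries its transgene within Commd10, and the labels do not say which line was used. Such an insertion may raise tags of the locus where Vav1 is active: the excess over control was 7.41 CPM in erythroid cells, which had the least Vav1, and had a median of 40.9 CPM over the other classes. It did not follow Vav1 class by class, and the transgene is present only in the knockout, so it cannot be told apart from an effect of Brd9 loss. The sex mix is argued against by a log2 ratio of at least 0.83 within each sex. The 7 genes within 2 Mb had a median absolute ratio at percentile 65.8 of random lists. This argues against passenger DNA that shifts most of them, but a median cannot decide about a change in fewer genes.

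Hbb-bt was lower in the knockout library in each class. Reads moved to its near-identical neighbour Hbb-bs would keep their sum. This argues against moved reads as the whole cause in erythroid cells, where the sum gave -0.50 and lay -0.77 from the alpha globins. It also does so in female cells, where the sum gave -0.80. In male cells the sum gave -0.16, too near 0 to decide by itself. There it lay -0.71 from the alpha globins, which argues against moved reads as the whole cause by the measure used for erythroid cells. These sums cannot decide about reads dropped for matching both genes, since such a loss would lower the sum. Fewer mature red cells are argued against as the whole cause by the alpha globins, at 0.27 in erythroid cells. A beta-globin haplotype carried by some embryos may account for it and cannot be told apart from the genotype: the Hbb-bt share of both genes differed by at least -24.9 percentage points in each class, although part of the UMIs outside erythroid cells may be free erythroid RNA. The share was 18.8% and 51.0% in erythroid cells, and over all classes 21.5% in female and 15.6% in male knockout cells against 51.4% and 51.2% in the control, and the locus was not typed here.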

How the results depend on the processing

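Settings that separate female and male cells, clustering without markers, leaving out cells with transcripts of both sexes or the top cell of a gene, and the choice of 4 lists to lead with, came after seeing the data. Over 50 alternative values of the lineage ratios, 11 left the main interval and 0 of the ratios whose interval excluded 1 reversed. For granulocyte-monocyte-lymphoid cells the ratio was 0.646 with knockout cells projected on control clusters, 0.641 under the stricter filter and 0.895 in female cells. For megakaryocyte and MEP cells it was 1.56 with cell-cycle genes kept. For erythroid cells it was 0.972 when projected, 0.968 under the stricter filter, 0.946 with cell-cycle genes kept and 0.952 in female cells, each with an interval below 1, unlike the main ratio. For HSC/MPP it was 0.770 in female cells, 1.17 in male cells and 1.20 under the first rule for sex. Brd9 gave -1.84 in female and -2.19 in male cells.

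List medians moved more. The stem cell programme gave 0.0059 at 100 CPM or more, 0.26 in female and 0.23 in male cells, membrane genes -0.033 at 100 CPM or more and -0.15 in female cells, and glycolysis 0.17 and 0.16 in female and male cells. Primary granule genes gave -0.48 with reweighted classes, -0.62 in female and -0.79 in male cells. Reversed medians were adult globins at -0.029 and unfolded protein response genes at 0.0071 in female cells, and sorting antigens at 0.072 with reweighted classes and 0.12 in female cells.

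Over 192 alternative values of whole-library genes 0 reversed, and over 1064 within classes 11 did. Chgb in HSC/MPP had no value without its top cells. In male cells Kdm6a gave -0.078 in HSC/MPP, -0.021 in GMP, -0.021 in MEP and -0.21 in monocytes, and -0.20 in female mast cells. In female cells Pold2 gave -0.20 in HSC/MPP and -0.26 in monocytes, Dhps 0.19 in mast cells, Rinl -0.043 and S100a8 -0.10 in monocytes. S100a9 gave -0.45 in projected monocytes. The cause was not tested. Median-of-ratios scaling shifted whole-library log2 ratios by -0.04 and, within classes, moved 26 of 183 values and reversed 0. Summed UMIs were fewest in HSC/MPP among the compared classes, and Brd9 rested there on 43 knockout UMIs. The 5th and 95th percentiles of the log2 ratio lay further apart in mast and basophil cells, at -0.29 and 0.38, than in HSC/MPP, at -0.22 and 0.32.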

Other observations

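Some genes outside the fixed lists, chosen after their values were seen, had the same direction in both sexes. Muc13, a membrane mucin, was at 3.87 against 12.5 CPM, with a log2 ratio of -1.63 in female and -1.85 in male cells. Apoc1, a neighbour of Apoe, was at 4.47 against 18.4 CPM, with -2.09 in GMP (-2.27 to -1.92). Alox5 was at 9.72 against 3.95 CPM, with 1.62 in GMP (1.40 to 1.84). In HSC/MPP, Hbb-bt made up 82.6% (80.9 to 84.2) of Hbb-bt and Hbb-bs UMIs in the control and 57.7% (53.1 to 62.2) in the knockout library, against 51.0% and 18.8% in erythroid cells of the same libraries. Free erythroid RNA would carry the erythroid share, which argues against it as the whole source of these HSC/MPP UMIs. Part of the HSC/MPP globin UMIs may still be free erythroid RNA.

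Genes around Brd9 did not stand apart: 11 genes within 2 Mb had a median absolute log2 ratio of 0.03, at percentile 13.7 of random lists. The barcodes left out by the filter had a median of 3054 and 3473 UMIs and 20.4% and 20.6% mitochondrial UMIs in knockout and control.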
